A study of Homo sapiens with 24 samples.

How the data were processed

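Messenger RNA was sequenced in 24 libraries from 2 human cholangiocarcinoma cell lines, RBE and SNU1079. The labels describe both lines as IDH1-mutant and as expressing SULT1A1. Cells received YC-1 or its solvent DMSO for 6 h or 16 h, which gives 8 groups of 3 libraries, called biological replicates in the design text. The labels give no dose. Per the labels' protocols, RNA was isolated with Qiagen RNeasy Plus and libraries were made with the TruSeq Stranded mRNA kit.

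Times were taken from the sample titles and the design text. A separate time label contradicts them, because it gives 16 h for every DMSO sample and 6 h for every YC-1 sample. A comparison with both times pooled was therefore planned as an alternative.

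The authors deposited normalised counts per gene, a signal that is neither raw counts nor scaled to a fixed library total. STAR and DESeq2 were used by the authors with genome build hg38, per the submitters' processing notes, which give no versions. The counting tool, strand setting and annotation release are not given in the sources used here. Low values did not fall on multiples of a single step per library. Between 35.4% and 68.6% of them lay within 0.1 of a whole multiple of the commonest value, so whole reads could not be recovered. Tests that need raw counts were not run. Sums of the normalised counts ran from 19010000 to 27010000 per library. Dividing by the commonest low value gave a rough depth of 12020000 to 41000000 reads, an approximation that assumes this value stands for 1 read.

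The table held 57820 rows, of which 24157 were at 0 in every library. Symbols were given for 35049 rows, 27 of them turned into dates by a spreadsheet. Names for 4727 rows were added from a table of gene identifiers. Rows without a symbol held 1.07% to 1.48% of the signal per library. Genes were tested when the normalised count was at least 10 in at least 3 libraries, which left 17860 genes. Coordinates came from GENCODE 29 on GRCh38 by matching Ensembl identifiers, which succeeded for 17258 tested genes (96.6%). No coordinate came from the deposited table.

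The values were analysed as log2(normalised count + 1) with limma 3.58.1 in R 4.3.3. One mean was fitted per group over all 24 libraries, with 16 residual degrees of freedom, and the moderated test used an intensity trend. All p-values are two-sided, and adjusted p-values are Benjamini-Hochberg values over the genes tested. The threshold was an adjusted p under 0.05. Fold changes are on the log2(normalised count + 1) scale, which understates changes of low genes. Tests covered YC-1 against DMSO in each line at each time, the 4 differences between those effects, and DMSO at 16 h against 6 h in each line. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1.

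Before the data were examined, 28 gene lists were fixed and tested with camera at a preset correlation of 0.01. Adjustment covered all lists and the 4 comparisons of YC-1 with DMSO. Camera with an estimated correlation and fry were run beside it. Members without a match in the table included UHRF1, BOP1, CD24 and PECAM1.

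Named genes followed a rule fixed at the same time. For each comparison of YC-1 with DMSO it takes the 10 highest and 10 lowest fold changes among called genes. These need a mean of at least 100 in the higher group and all YC-1 libraries beyond all DMSO libraries. It adds 5 shared genes per direction and time, 5 genes per direction for each difference of effects, up to 4 members per list, and 14 genes of interest including SULT1A1. The genes for differences of effects need a call and a mean of at least 100 in the highest group compared, without separated libraries. Genes singled out outside this rule are identified where they appear. Values of a few genes under the rule are not reported here.

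The tests were checked on simulated values for YC-1 against DMSO in RBE at 6 h, over 17216 genes. Changes of log2 size 1 were recovered for 54.5% of 99 genes and those of size 2 for 90.7% of 97 genes, and 7.8% of the 154 calls were false. Alternatives covered the pseudocount, the filter, 3 other scalings, the variance model, the libraries entering the fit, the replicate number as a block, pooled times, a minimum fold change and the removal of each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.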

Results

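The series measured how the transcriptome of RBE and SNU1079 cells changed under YC-1, a benzylindazole known as an activator of soluble guanylate cyclase and as an inhibitor of HIF-1. Its title concerns the sensitivity of liver-lineage cancers to alkylators that depend on sulfonation. Each of the 8 groups held 3 libraries. Summed normalised counts were 19010000 to 21580000 in the DMSO libraries and 20430000 to 27010000 in the YC-1 libraries. The first principal component (62.0% of the variance) separated the lines, and the second (17.6%) ran from DMSO over YC-1 at 6 h to YC-1 at 16 h.

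SULT1A1, a cytosolic sulfotransferase (ENSG00000196502, chromosome 16, 28605196 to 28623625), was present in every group at means between 1415 and 1792. Its level did not pass the test for YC-1 in RBE at 16 h (1792 ± 124 against 1551 ± 112, SD, n = 3, adjusted p = 0.28) or in the other 3 comparisons. SULT1A2 rose in SNU1079 at both times and in RBE at 16 h, and SULT1A3 rose in SNU1079 at 16 h (1.24 ± 0.30, log2 fold change ± SE). Of the 15 sulfonation genes tested, 3 rose and 1 fell in RBE and 4 rose and 3 fell in SNU1079 at 16 h, or 2 and 1 and 4 and 1 when adjusted over the list alone. The SNU1079 call at 6 h, SULT1A2 (0.57), was lost on that basis. The RBE values at 16 h for SULT1A1, SULT1A2 and SULT1A3 turned to lower when libraries were scaled to ribosomal protein genes. Of those 50 reference genes, 49 were themselves called higher there (median 0.94), so this scaling lowers the values of other genes. SULT1A2 stayed higher when libraries were scaled to equal sums. These genes are similar in sequence, and their values are uncertain where reads were split between similar genes. PAPSS1 and PAPSS2, which make the sulfate donor, did not pass in any comparison of YC-1 with DMSO. The sulfate transporter SLC26A2 fell by 1.42 in each line at 16 h, and SULT1C4 rose at 16 h from 0.8265 ± 0.152 to 12.67 ± 2.47 in RBE and from 0.864 ± 0.855 to 37.46 ± 18.1 in SNU1079 (SD, n = 3).

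**Figure D1:**
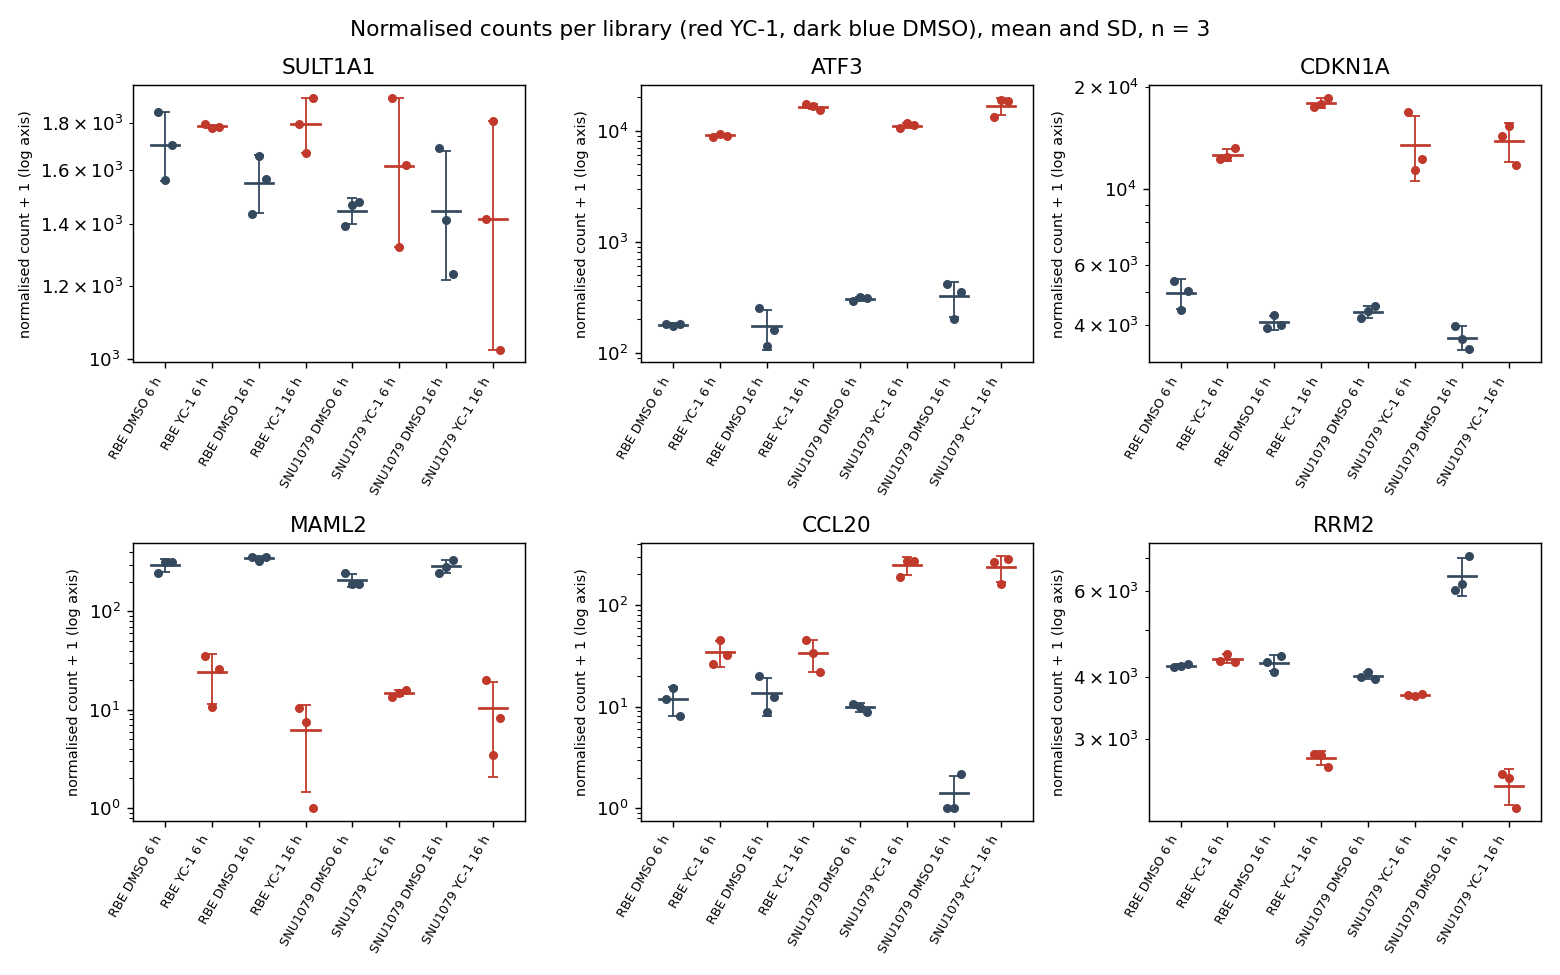
Normalised counts plus 1 on a log axis for 6 genes in the 8 groups, with points for libraries, lines for means and bars for SD (n = 3). ATF3 lies between 9068 and 16830 on average in the YC-1 groups and between 174.6 and 320.9 in the DMSO groups, while SULT1A1 stays between 1415 and 1792.

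After 6 h in RBE, genes of the ATF4 and CHOP stress response were higher with YC-1, and several genes of cholesterol synthesis and the heat shock response were lower. ATF3, a stress-induced transcription factor, went from 177.9 ± 5.7 to 9068 ± 326 (SD, n = 3), a log2 fold change of 5.66 ± 0.22 (SE). FOS (4.64), NR4A3 (4.91), EGR1 (3.88) and RND1 (4.05) rose with it. Among the genes with the lowest fold changes were MAML2, a Notch coactivator (-3.78), EFNA5 (-3.00), JARID2 (-2.97) and FUT8 (-2.80). In all, 4290 genes passed the test, 2069 up and 2221 down, and 6760 passed when only the 12 RBE libraries were fitted.

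Of 24 tested genes of the ATF4 and CHOP stress response, 20 rose and none fell in RBE at 6 h (camera adjusted p = 7.08e-18, and 0.000494 with an estimated correlation). DDIT3, which encodes CHOP, rose by 3.24 and PPP1R15A by 2.65. p53 targets gave 17 up and 0 down of 27 (adjusted p = 1.52e-08), led by BTG2 (2.36), GDF15 (3.16) and the cell cycle inhibitor CDKN1A (1.36). MDM2, another member, stood at 4335 ± 401 against 4230 ± 182 (SD, n = 3) and did not pass. Adjusted over the list alone, 20 stress response and 17 p53 genes rose as well. Immediate early genes gave 16 up and 5 down of 30, with adjusted p = 6.52e-07 and adjusted p = 0.0545 with an estimated correlation. These counts were 18 and 5 when adjusted over the list alone.

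Cholesterol synthesis genes were lower in RBE at 6 h, with 8 of 21 down and none up (adjusted p = 0.00015). INSIG1 fell by 2.05 and SQLE by 1.16 on the log2 scale. Heat shock genes gave 6 down of 19 (adjusted p = 2.55e-05), and the chaperone HSPA8 fell by 1.22. Nucleolar ribosome biogenesis genes gave 11 up and 2 down of 27 (adjusted p = 0.000172), with NOP2 at 1.04. NF-kB and cytokine genes gave 9 up and 2 down of 20 (adjusted p = 0.0143), with CXCL8 at 2.25. These 4 lists also passed with an estimated correlation. Adjusted over the list alone, 8 cholesterol and 8 heat shock genes fell, nucleolar genes gave 12 up and 3 down, and cytokine genes 9 up and 3 down. Host transcripts of small nucleolar RNAs gave 10 up and 0 down of 14 (GAS5 at 1.18), with adjusted p = 0.0681 with an estimated correlation. Mitotic genes gave 10 down of 28 (AURKA at -0.88), with adjusted p = 0.317 with an estimated correlation. Splicing factors (10 up, 2 down of 44) and polymerase II genes (13 up, 4 down of 36) had adjusted p = 0.145 and adjusted p = 0.0554 with an estimated correlation. For these 4 lists, adjusted over the list alone, 11 host transcripts rose, 13 mitotic genes fell, and the counts of the last pair were the same.

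At 16 h in RBE the fold changes of ATF3 (6.63), FOS (6.25) and NR4A3 (5.43) were again among the highest. NHLH1 and C1orf162 joined them, with NHLH1 at 147.4 ± 8.39 against 0.2426 ± 0.42 (SD, n = 3). MAML2 fell from 349.1 ± 18 to 5.285 ± 4.82 (SD, n = 3), and EPHB1 (-4.85), ZNF407 (-4.53), PPARGC1B (-4.38) and NAV2 (-4.21) were also lower. The test called 9621 genes, 4867 up and 4754 down. Scaling libraries to equal sums changed this split to 2904 up and 6474 down, so the direction of small changes at 16 h rests on the scaling. Mitochondrial transcripts held 16.2% ± 0.83 of the signal with YC-1 and 7.86% ± 0.27 with DMSO (SD, n = 3).

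p53 targets (22 up, 1 down of 27, CDKN1A at 2.14) and stress response genes (19 up, 2 down of 24, SLC3A2 at 2.65) passed in RBE at 16 h with both correlations. Cholesterol synthesis genes did too, with 14 down and 1 up of 21. SQLE fell by 2.87 on the log2 scale. Ribosomal protein genes gave 49 up of 50 (RPL12 at 1.40), with adjusted p = 0.123 with an estimated correlation. That direction is removed by construction when libraries are scaled to these genes, which moves log2 fold changes by a median over genes of -0.92. Host transcripts of small nucleolar RNAs gave 13 up of 14 (ZFAS1 at 2.31), with adjusted p = 0.0545 with an estimated correlation. Mitotic genes (18 down, 3 up of 28, AURKA at -2.02) and repair genes of the Fanconi anaemia list (11 down, 2 up of 22, BRIP1 at -1.87) had adjusted p = 0.292 and adjusted p = 0.315 with it. HIF-1 targets gave 13 up and 4 down of 30 (adjusted p = 0.0476, and adjusted p = 0.14 with an estimated correlation). ADM rose by 3.21 and LDHA (-1.21) and PFKFB3 (-1.89) fell, while TPI1, like LDHA a glycolytic gene, rose by 0.98, a call lost with scaling to ribosomal protein genes (0.05). Adjusted over the list alone, p53 targets gave 23 up and cholesterol genes 15 down, and the other lists described here gave the same counts.

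In SNU1079 at 6 h, ATF3 went from 305.9 ± 12.5 to 11130 ± 557 (SD, n = 3). FOS (4.78), the chemokine CCL20 (4.63), NR4A3 (4.46) and CHAC1, a glutathione-degrading enzyme (4.11), were also higher. MAML3 (-4.85), MAML2 (-3.81), the phosphodiesterase gene PDE4D (-3.77) and GLI2 (-3.46) were lower. The test called 5042 genes, 2499 up and 2543 down. One library of this YC-1 group, replicate 1, stood apart from its group mates, together with a DMSO and a YC-1 library at 16 h. Without these 3 libraries, an alternative chosen after seeing the data, 6362 genes were called, and 3332 when only the 12 SNU1079 libraries were fitted.

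Stress response genes gave 19 up and 1 down of 24 in SNU1079 at 6 h, with ASNS, asparagine synthetase, at 2.83. p53 targets gave 11 up and 1 down of 27 (CDKN1A at 1.61). G1/S and DNA replication genes gave 13 down and none up of 26 (adjusted p = 2.65e-08), with FEN1 falling by 1.54 and MCM3 by 0.65. Immediate early genes gave 18 up and 1 down of 30 (DUSP4 at 2.17). All 4 lists passed with an estimated correlation. Repair genes (10 down of 22, BRIP1 at -1.53) and mitotic genes (8 down of 28, BUB1B at -0.80) had adjusted p = 0.131 and adjusted p = 0.395 with it. Ribosomal protein genes (9 up of 50), splicing factors (15 up, 3 down of 44) and cytokine genes (10 up, 4 down of 20) had adjusted p = 0.46, adjusted p = 0.16 and adjusted p = 0.0545 with it. Host transcripts of small nucleolar RNAs gave 11 up of 14, with adjusted p = 0.0545 with an estimated correlation. Adjusted over the list alone, 20 stress response, 13 p53 and 19 immediate early genes rose and 1, 1 and 3 fell. On that basis 14 replication and 12 repair genes fell, 7 ribosomal protein genes and 16 splicing factors rose, and 1 host transcript fell. Under scaling to ribosomal protein genes the split of all calls was 1394 up and 3386 down. Without the 3 libraries that stood apart, 8 lists were called higher and 2 lower, where the main fit called 7 and 3.

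In SNU1079 at 16 h, cytokine genes and mitotic genes changed together with the stress response. NF-kB and cytokine genes gave 15 up and 3 down of 20 (adjusted p = 1.9e-06, and 0.000827 with an estimated correlation). CXCL8 went from 147.3 ± 6.11 to 6825 ± 1190 and CCL20 from 0.3925 ± 0.68 to 236.5 ± 67.9 (SD, n = 3). The DMSO baseline differed from that at 6 h, with 13 of the 20 cytokine genes lower in DMSO at 16 h (median -1.45, and 16 adjusted over the list alone). CXCL8 stood at 712.7 ± 96.6 with DMSO and 5809 ± 1240 with YC-1 at 6 h. Mitotic genes gave 26 down and none up of 28 (adjusted p = 1.46e-13, and 0.0463 with an estimated correlation), with CENPF falling by 2.52 and AURKA by 2.47. Here the DMSO baseline was higher at 16 h than at 6 h for 21 of the 28 (median 0.79, and 27 adjusted over the list alone), with CENPF going from 3891 ± 153 to 8008 ± 617. G1/S and replication genes gave 21 down of 26 (RRM2 at -1.42), with 8 higher in DMSO at 16 h than at 6 h (13, and 1 lower, adjusted over the list alone) and RRM2 there going from 4030 ± 69 to 6432 ± 567 (SD, n = 3). Stress response genes gave 21 up and 1 down of 24 (ASNS at 3.36) and p53 targets 14 up and 2 down of 27 (CDKN1A at 1.91). All 3 of these lists passed with an estimated correlation. Adjusted over the list alone, 22 replication genes fell and 1 rose, 15 p53 targets rose, and the counts of cytokine, mitotic and stress response genes were the same.

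Repair genes gave 16 down and 1 up of 22 (BRCA1 at -1.96), with adjusted p = 0.0545 with an estimated correlation. In DMSO, 5 of these 22 were higher at 16 h than at 6 h (7 adjusted over the list alone), and BRCA1 went from 1577 ± 207 to 2651 ± 354 (SD, n = 3). Ribosomal protein genes (40 up, 1 down of 50, RPL12 at 1.14) and nucleolar genes (15 up, 6 down of 27, NOP2 at 1.39) had adjusted p = 0.315 and adjusted p = 0.13 with it. In DMSO, 14 of the 27 nucleolar genes were lower at 16 h than at 6 h (17 adjusted over the list alone). Host transcripts of small nucleolar RNAs gave 13 up of 14 (GAS5 at 2.34), with adjusted p = 0.0545 with it. In counts adjusted over the list alone, 17 repair genes fell, and 41 ribosomal protein genes, 15 nucleolar genes and 14 host transcripts rose. The lowest fold changes included B3GALT1 (-5.46), PDE4D (-5.30), MAML2 (-5.11), VAV3 (-5.09) and TCF7L2, a Wnt pathway transcription factor (-4.39). The test called 9741 genes, 5130 up and 4611 down, and scaling to equal sums gave 3068 up and 6598 down. Fitting only the 6 libraries compared gave 6363. Mitochondrial transcripts held 18.1%, 3.38% and 22.1% of the signal in YC-1 replicates 1, 2 and 3, against 7.57% ± 1.36 with DMSO (SD, n = 3).

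**Figure D2:**
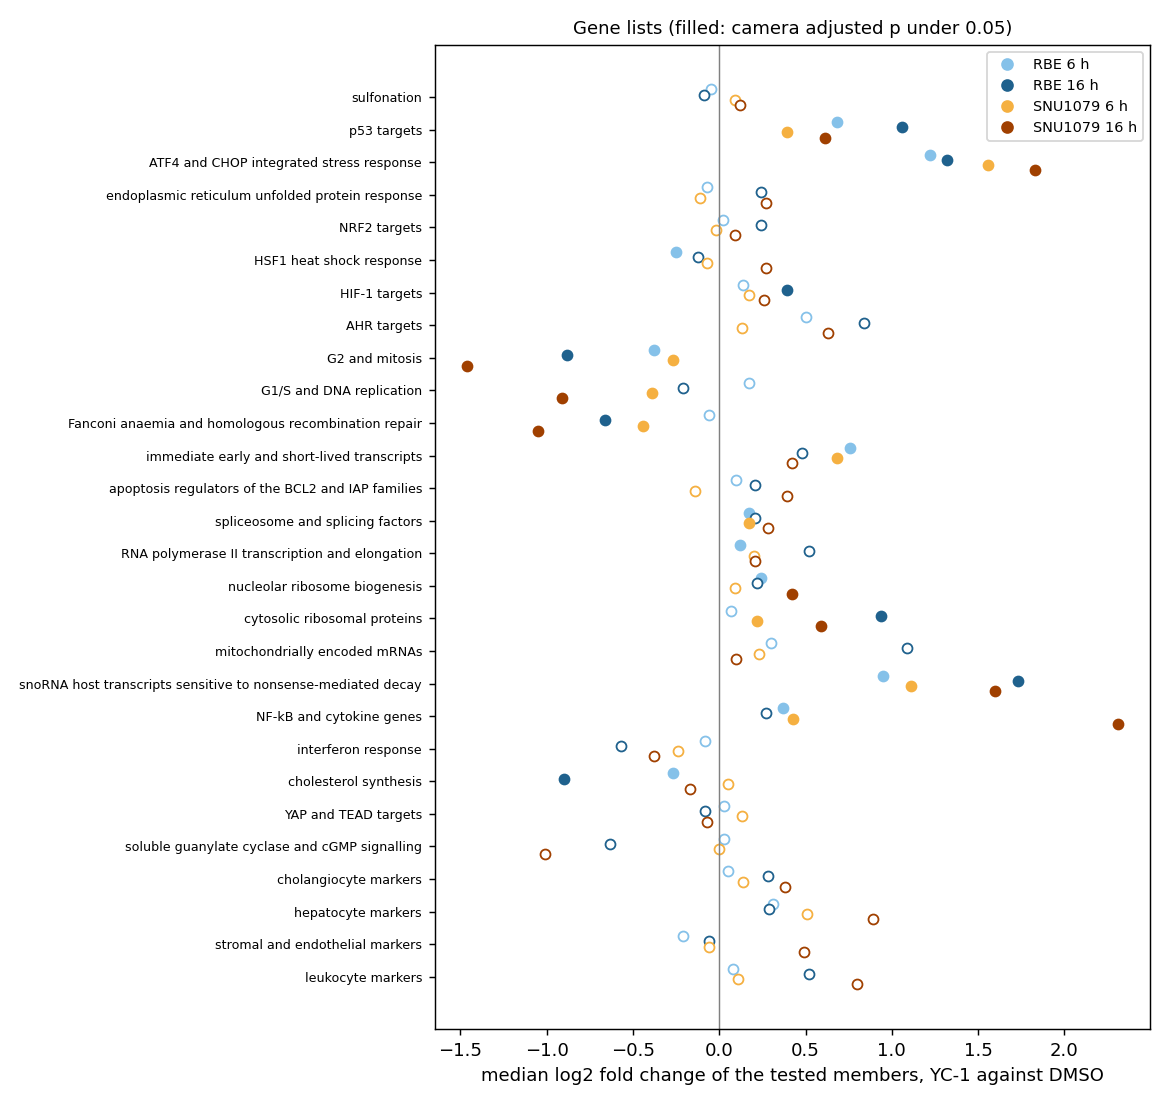
Median log2 fold change of the tested members of each of the 28 gene lists, 1 point per comparison of YC-1 with DMSO, filled where camera passed at the preset correlation. Stress response genes have medians of 1.22 to 1.83, and mitotic genes reach -1.46 in SNU1079 at 16 h.

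Several lists did not pass in any of the 4 comparisons. These were sulfonation, the unfolded protein response, NRF2 targets, AHR targets, apoptosis regulators, mitochondrially encoded mRNAs, interferon response, YAP targets, cyclic GMP signalling and the markers of cholangiocytes, hepatocytes, stromal and endothelial cells, and leukocytes. The lowest camera adjusted p among them was 0.0565, for AHR targets in RBE at 6 h. Mitochondrially encoded mRNAs had a median of 1.09 in RBE at 16 h, with 1 of 13 called higher. MT-CO1 there went from 313300 ± 11700 to 876500 ± 43700 (SD, n = 3). The fit pools the spread of all groups, and MT-CO1 stood at 707900 ± 540000 with YC-1 in SNU1079 at 16 h. Not passing therefore does not show that these mRNAs were unchanged in RBE. Camera compares a list with the other genes, so lists that did not pass could still hold many changed members. In RBE at 16 h, 9 of 18 unfolded protein response genes rose and 5 fell. In SNU1079 at 16 h, 10 of 22 NRF2 targets rose and 6 fell (7 adjusted over the list alone). Of 9 cyclic GMP genes there, 1 rose and 5 fell. Of all genes tested, 53.9% and 54.5% were called in RBE and SNU1079 at 16 h. XBP1, in the unfolded protein response list, rose by 1.48 in RBE at 6 h. GUCY1A3, a subunit of soluble guanylate cyclase, fell by 2.08 in RBE and by 2.07 in SNU1079 at 16 h. The short-lived transcripts of MCL1, an antiapoptotic protein, fell by 1.40 and 1.36 at 16 h, and MYC fell by 1.29 and 0.68 at 16 h after rising by 0.47 in RBE at 6 h (0.26 in SNU1079, adjusted p = 0.0938). HIF1A did not pass in SNU1079 at 16 h (0.00 ± 0.14, SE), where scaling to equal sums gave -0.36. With DMSO and YC-1 its levels were 9614 ± 713 and 7610 ± 166 in RBE at 16 h and 8249 ± 918 and 8545 ± 441 in RBE at 6 h. In SNU1079 at 6 h they were 10800 ± 1100 and 9783 ± 722 (SD, n = 3).

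The lines shared much of the response. At 6 h, 1364 genes rose and 1499 fell in both, where independent lists would share 289.5 and 316.2. At 16 h these counts were 3451 and 3285, against 1398 and 1227.4. Fold changes of the lines correlated across genes with Spearman's rho of 0.62 at 6 h and 0.72 at 16 h, although genes are not independent replicates. ATF3, FOS, NR4A3 and RND1 were among the shared genes with the highest fold changes at 6 h, and MAML2, RGL1, EFNA5, GLI2 and JARID2 among the lowest. Across all 4 comparisons, 1104 genes rose and 1339 fell.

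**Figure D3:**
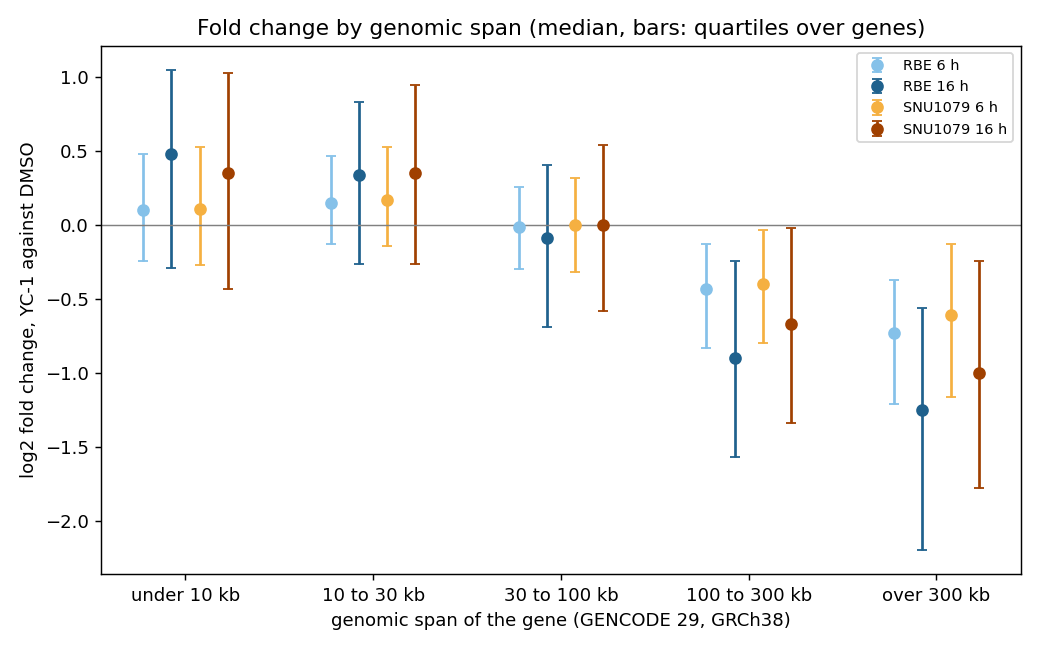
Log2 fold change of YC-1 against DMSO for genes grouped by genomic span, with points for medians and bars for quartiles over genes. Medians lie between 0.10 and 0.48 under 10 kb and between -1.25 and -0.61 over 300 kb.

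Genes covering long stretches of the genome were lower after YC-1, a property examined after such genes were seen among the lowest fold changes. In RBE at 16 h, 65.1% of 590 genes spanning over 300 kb fell and 2.4% rose, whereas 13.8% of 4832 genes under 10 kb fell and 38.3% rose. SNU1079 at 16 h gave 59.3% and 4.7% against 16.7% and 35.5%. MAML2 (chromosome 11, 95976598 to 96343180, GRCh38) and NAV2 (chromosome 11, 19350724 to 20121598) are examples. Spearman's rho of fold change with span across 17258 genes was -0.32 and -0.41 in RBE and -0.27 and -0.31 in SNU1079, at 6 h and 16 h. Given transcript length, transcript GC content and mean level, the correlations were weaker, at -0.264 and -0.241 in RBE and -0.197 and -0.186 in SNU1079.

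The effect of YC-1 differed between times for 3256 genes in RBE and 3036 in SNU1079. Of these, 2363 and 2038 had the same sign at both times and a larger change at 16 h. DKK1, a Wnt antagonist, changed by 0.05 at 6 h and -3.32 at 16 h in RBE, a difference of -3.37 ± 0.33 (SE). GBP1, an interferon-inducible GTPase, differed by 3.04 ± 0.26 (SE) in SNU1079, where its DMSO level went from 642.3 ± 53 at 6 h to 86.4 ± 17.3 at 16 h and its YC-1 level stood at 484.2 ± 98.7 and 529.3 ± 56.1 (SD, n = 3). Scaling to equal sums changed the split from 1571 up and 1685 down to 567 and 3437 in RBE, and from 1512 and 1524 to 499 and 3239 in SNU1079. The SNU1079 count was 4691 without YC-1 6 h replicate 1 and 5343 without the 3 libraries that stood apart, but 1078 when only the 12 SNU1079 libraries were fitted, which for RBE gave 6229.

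Between the lines the effect differed for 275 genes at 6 h and 2608 at 16 h. CCL20 rose more in SNU1079, by 3.07 ± 0.54 at 6 h and 6.16 ± 0.54 at 16 h (SE). Its SNU1079 level with YC-1 was 244.9 ± 48.1 and 236.5 ± 67.9, while that with DMSO went from 8.806 ± 0.952 to 0.3925 ± 0.68 (SD, n = 3). EGR1 rose by 4.09 in RBE at 16 h and stood at 0.40 in SNU1079 (adjusted p = 0.203), a difference of -3.69 ± 0.37 (SE). In SNU1079 EGR1 rose by 2.71 at 6 h, from 54.84 ± 5.44 to 363.9 ± 34.6, and at 16 h stood at 246.2 ± 38.3 with DMSO and 338.4 ± 130 with YC-1 (SD, n = 3). CYP1A1, a target of the aryl hydrocarbon receptor, rose by 1.66 in RBE and fell by 1.25 in SNU1079 at 6 h. Its SNU1079 levels were low, at 45.89 ± 13.7 with DMSO and 18.4 ± 4.1 with YC-1 (SD, n = 3). CYP1B1, another such target, went from 1713 ± 160 to 4707 ± 258 in RBE and from 1738 ± 227 to 4277 ± 75.4 in SNU1079 at 6 h. Of the 7 AHR targets tested, 3 rose and 0 fell in RBE, and 3 rose and 1 fell in SNU1079, at 6 h. Without the 3 libraries that stood apart, 1153 genes differed at 6 h and 4027 at 16 h. These libraries were chosen for their deviation, so a lower residual spread alone can raise such counts.

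DMSO at 16 h was compared with DMSO at 6 h as the background of the effects over time, without separating time in culture from handling or preparation. In RBE 8 genes passed, 1 up and 7 down, with 688 at an unadjusted p under 0.05, and in SNU1079 1530 passed, 682 up and 848 down. FHL2 (-0.75) was among the RBE genes and is named after its value was seen. The SNU1079 calls included mitotic, cytokine and nucleolar genes, counted by list after the calls were seen. The number of all calls in SNU1079 was 3272 without the 3 libraries, and between 908 and 936 when any 1 of the 6 h DMSO libraries was left out. Fitting only the 12 libraries of a line gave 469 in SNU1079 and 68 in RBE.

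**Figure D4:**
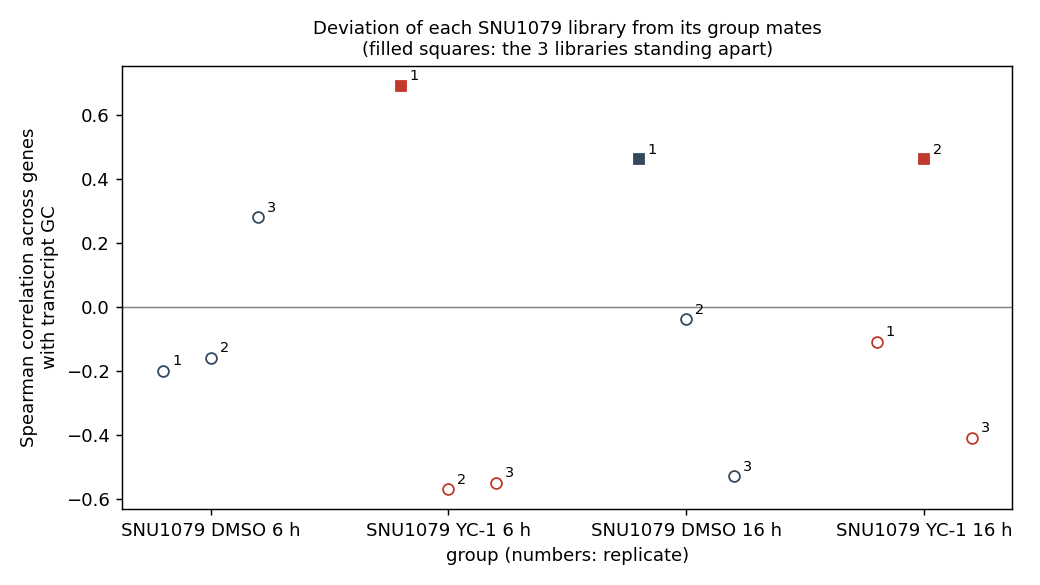
Spearman correlation across genes between transcript GC content and the deviation of each SNU1079 library from the other libraries of its group, with numbers for replicates. The 3 filled libraries lie at 0.46, 0.46 and 0.69, and 4 of their group mates between -0.57 and -0.41, where part of the opposite sign follows from taking each deviation within the group.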

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

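The tests of long-gene effects over time, of exchanged treatment labels and of RNA from RBE cells were chosen after their results had been at least partly seen, and so was the analysis without 3 SNU1079 libraries. Groups of 3 were not tested for single outlying libraries.

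The effect of YC-1 differed between 16 h and 6 h for 3256 genes in RBE and 3036 in SNU1079, by tests of the difference itself. The genes named next have the largest differences among called genes with a mean of at least 100 in the highest group compared. In RBE these were KRBA2 (3.23), MYH3 (3.21), AOC3 (3.17), C1orf162 (2.88) and NHLH1 (2.52) upwards. Downwards they were DKK1 (-3.37), TANC2 (-2.79), LRRN2 (-2.69), ART4 (-2.64) and INHBA (-2.49). In SNU1079 they were GBP4 (3.99), MALAT1 (3.24), GBP1 (3.04), PALM2 (2.99) and WNT4 (2.85) upwards and PCLO (-2.94), VAV3 (-2.88), NR5A2 (-2.65), NHS (-2.59) and ELMSAN1 (-2.45) downwards. DMSO levels in SNU1079 differed between 6 h and 16 h for several of these, going from 642.3 to 86.4 for GBP1, 102.2 to 8.156 for GBP4, 136.8 to 23.41 for WNT4 and 94.25 to 347.5 for VAV3. YC-1 levels were 484.2 ± 98.7 and 529.3 ± 56.1 for GBP1, 41.35 ± 43.8 and 46.68 ± 44.7 for GBP4, and 71.74 ± 28.2 and 85.1 ± 16.5 for WNT4 (SD, n = 3). PCLO stood at 184.5 ± 166 with DMSO and PALM2 at 153.6 ± 95.4 with YC-1 in SNU1079 at 16 h. The values of PCLO, PALM2 and GBP4 are uncertain because of these spreads.

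Between the lines the effect differed for 275 genes at 6 h and 2608 at 16 h. At 6 h the values of SNU1079 against RBE were THSD1 (3.52), ARHGAP31 (3.41), KIAA1549L (3.25), CCL20 (3.07), PGBD1 (2.80), PDE4D (-4.41), CYP1A1 (-2.91), NHS (-2.38), EMC3-AS1 (-2.32) and RGS16 (-2.29). At 16 h they were SFT2D3 (7.02), CCL20 (6.16), ARHGAP31 (5.56), SV2A (4.97), KIAA1549L (4.74), NHS (-4.96), SPSB4 (-4.12), PDE4D (-4.11), GRHL3 (-4.11) and EGR1 (-3.69). SFT2D3, NHS and SPSB4 are listed at 0 in every RBE library, so their values describe SNU1079 alone. SFT2D3 was also at 0 with DMSO in SNU1079 and stood at 161 ± 118 with YC-1 at 16 h (SD, n = 3), so its value is uncertain. Mean DMSO levels in SNU1079 were also near 0 for KIAA1549L and ARHGAP31 (0.9254 and 1.009 at 6 h) and for SV2A and GRHL3 (0 and 3.188 at 16 h). RGS16 stood at 0.7031 with DMSO in RBE at 6 h. The differences of these genes rest partly on values near 0 in at least 1 line.

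Chance was tested by regrouping the same libraries, for differences of effects after removing the mean of each time or line from every gene. Of 100 regroupings for each difference of effects, 1 called as many genes as the real one for time in RBE (3256, highest other 2), for line at 6 h (275, highest other 1) and for line at 16 h (2608, highest other 302), the real one included. This share is under 0.05 and argues against chance there without excluding it. For time in SNU1079, 4 of 100 called as many (3036, highest other 4993), a share still under 0.05. The other 3 all put YC-1 6 h replicate 1 together with YC-1 16 h replicates 1 and 2, which points to a structure among these libraries. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and 1 of 10 was as large in each case. The real counts and highest others were 4290 and 1 (RBE 6 h), 9621 and 2 (RBE 16 h), 5042 and 2 (SNU1079 6 h), 9741 and 457 (SNU1079 16 h), and for DMSO over time 8 and 3 (RBE) and 1530 and 6 (SNU1079).

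DMSO 16 h replicate 1, YC-1 6 h replicate 1 and YC-1 16 h replicate 2 of SNU1079 deviated together, with pairwise residual correlations of 0.21 to 0.34. Their mean deviation correlated with transcript GC content across genes (rho 0.668, with single values down to -0.57 in their group mates), which is consistent with a difference in library preparation. Exchanged treatment labels are argued against, because each library lay at 0.786 or more of the way to its own treatment group. RNA from RBE cells is argued against in both replicates 1, which were shifted towards RBE by at most -0.003. Genes expressed in RBE alone had a median of 0% of their RBE level in both. The highest stood at 1.057% in DMSO 16 h replicate 1 and at 0.196% in YC-1 6 h replicate 1. An admixture too small for these measures is not excluded. For YC-1 16 h replicate 2, shifted by 0.046, RNA from RBE cells stays open. In that library genes expressed in RBE alone had a median of 0.1198% of their RBE level, and the highest of 18 genes stood at 0.967%. These percentages cannot decide it, because the shift was taken on log2 values, where a small admixture moves such genes far. A difference in library preparation stays open, and no biological explanation was tested because the labels set these libraries in no group of their own.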

How the results depend on the processing

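The alternative without the 3 SNU1079 libraries was chosen after the results were seen. Leaving out libraries picked for their deviation lowers the residual spread, so higher counts there do not show a clearer effect. Tests that need whole reads (edgeR and DESeq2) were planned and not run, because whole reads could not be recovered. Of 10946 values of named genes under alternatives, 316 lost the call, 41 gained it and 21 changed sign with the main or the alternative value called. The other 10568 kept their side of the threshold, and they include changes of sign in which neither value was called. For these changes and the counts below the cause was not tested, unless a minimum fold change set it.

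Changes of sign with the main or the alternative value called came from 3 alternatives. Scaling to ribosomal protein genes gave, in RBE at 16 h, ACTA2 -0.09, CD68 -0.28, HEXIM1 -0.40, HSPA5 -0.20, HYOU1 -0.05, IRF1 -0.22, KRT8 -0.15, NQO1 -0.09, RPL14 -0.17, SERPINA1 -0.24, SLC35B2 -0.68, SULT1A1 -0.72, SULT1A2 -0.25, SULT1A3 -0.64, and TAGLN -0.06, and HIF1A -0.54 in SNU1079 at 16 h. Scaling to equal sums gave HIF1A -0.36 in SNU1079 and SLC35B2 -0.08 in RBE, both at 16 h. Pooling the times gave GUCY1A3 -1.02 and MYC -0.41 in RBE and HSPA6 0.12 in SNU1079, each set against the 6 h value.

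Scaling to equal sums moved log2 fold changes by a median over genes of -0.33 in RBE and -0.36 in SNU1079 at 16 h, TMM by -0.11 in SNU1079 at 16 h, and scaling to ribosomal protein genes by -0.92 and -0.54 at 16 h and -0.20 in SNU1079 at 6 h. The percentage of calls that were higher went from 50.6 to 31.0 (equal sums) and 9.1 (ribosomal protein genes) in RBE at 16 h, from 52.7 to 31.7 and 23.4 in SNU1079 at 16 h, and from 49.6 to 29.2 (ribosomal protein genes) in SNU1079 at 6 h. For the effect over time it went from 48.2 to 14.2 and 1.8 in RBE, with 8049 genes called in the latter case, and from 49.8 to 13.3 and 13.5 in SNU1079, with 39.6 under TMM. For the effect between lines ribosomal protein genes gave 89.6 at 16 h (main 55.9) and 36.5 at 6 h (main 49.8). For DMSO over time equal sums gave 57.0 in SNU1079 (main 44.6), and ribosomal protein genes gave 2 up and 2 down in RBE (main 1 and 7).

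An absolute log2 fold change of at least 1 left 1724 genes in RBE at 6 h, 5283 in RBE at 16 h, 2150 in SNU1079 at 6 h, 5502 in SNU1079 at 16 h and 4215 of the 9599 shared calls. Pooled times gave 8282 genes in RBE and 8465 in SNU1079 against the 6 h counts. Fitting only the 12 libraries of the line gave 6760 (RBE 6 h), 3332 (SNU1079 6 h), 6229 and 1078 (effect over time in RBE and SNU1079) and 68 and 469 (DMSO over time). These counts lay above the main ones in RBE and below them in SNU1079. The main fit pools the spread of both lines for each gene. Replicates of SNU1079 tended to vary more, with lowest correlations per group of 0.952 to 0.981 against 0.978 to 0.986 in RBE. Main counts for SNU1079 therefore rest partly on the spread of RBE libraries. Fitting only the 6 libraries compared gave 6363 in SNU1079 at 16 h. DMSO over time in RBE gave 15 with a filter of 50, 13 without a filter, 18 with a pseudocount of 0.1, 13 with a pseudocount of 10 and 4 with scaling to ribosomal protein genes, which gave 952 in SNU1079. The effect between lines at 6 h gave 456 with a pseudocount of 10. Without the 3 SNU1079 libraries the counts were 3272 (DMSO over time in SNU1079), 5343 (effect over time), 1153 and 4027 (effect between lines at 6 h and 16 h). With an estimated correlation 6, 3, 4 and 5 lists were called in RBE at 6 h and 16 h and SNU1079 at 6 h and 16 h, and fry, which compares no list with other genes, called 17, 23, 19 and 25.

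Leaving out each library in turn gave 3333 to 3709 (RBE 6 h), 8653 to 8873 (RBE 16 h), 4105 to 5001 (SNU1079 6 h), 8755 to 9696 (SNU1079 16 h), 2212 to 2828 (time, RBE), 2240 to 4691 (time, SNU1079), 190 to 412 (lines, 6 h), 1871 to 2924 (lines, 16 h), 4 to 16 (DMSO, RBE), 908 to 1337 (DMSO, SNU1079) and 8963 to 10153 shared calls. Lists called were 11 to 13, 6 to 9, 9 to 11 and 9 to 11. Single libraries moved a count by over 1.5 times for time in SNU1079 (4691 without YC-1 6 h replicate 1), DMSO in RBE (4 and 16 without 16 h replicates 1 and 3, 5 without 6 h replicate 3) and DMSO in SNU1079 (936, 908 and 932 without 6 h replicates 1, 2 and 3).

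Replicate numbers did not pair the libraries, since residual correlations of equal numbers ran from -0.21 to 0.34, and 2 of 12 RBE and 4 of 12 SNU1079 libraries correlated best with their own number. A replicate block within line and time gave 138 genes for lines at 6 h. No other count moved by over 1.5 times under a replicate block, and a block within line gave 210 there. In simulated RBE 6 h data 54.5% of changes of log2 size 1 were recovered. This share does not carry over to the real comparison. Few genes were changed in the simulation, and with 154 calls its adjusted threshold was stricter than with the 4290 real calls.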

Other observations

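The test of long-gene effects over time was chosen after its result had been partly seen, and the other tests in this part were set before their results were seen. POLR2A, the large subunit of RNA polymerase II, rose in all 4 comparisons, by 2.06 and 2.44 in RBE and 2.61 and 2.99 in SNU1079 at 6 h and 16 h. The splicing regulator SRSF6 rose by 1.13 and 1.55 at 6 h, while HNRNPA1, another splicing factor, fell by 0.81 and 1.03. MALAT1, a nuclear noncoding RNA, rose by 2.08 in RBE and 3.73 in SNU1079 at 16 h.

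Genes lower after YC-1 tended to span long genomic regions. Noise of weakly expressed genes is argued against, since rho with span was -0.432 or lower in the third of genes with the highest mean in every comparison. Transcript length and GC content cannot be told apart from span in part, because the correlation given both and the mean level was as weak as -0.186 in SNU1079 at 16 h, between the bounds set beforehand of -0.1 and -0.2. A hypothesis is that YC-1 may hinder completion of long transcription units, but the 16 h minus 6 h effect of genes over 100 kb against genes under 10 kb (-0.75 in RBE and -0.45 in SNU1079) does not decide it, because the pattern was there at 6 h (-0.60 and -0.54) and would widen with any effect that grew. RNA stability was not tested and stays open.

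RPL36A-HNRNPH2, a read-through locus joining neighbouring genes (chromosome X, 101391011 to 101412297, GRCh38), rose from 1.17 ± 2.02 to 373 ± 11 in RBE at 16 h (SD, n = 3) and was listed at 0 in the DMSO libraries of SNU1079. In 252 other loci annotated only as read-through transcripts, 14 rose and 12 fell in RBE at 6 h, 44 and 22 in RBE at 16 h, 32 and 6 in SNU1079 at 6 h, and 87 and 18 in SNU1079 at 16 h, so most were not called. Their median, 0.09 in the first of these and 0.91 in the last, lay at or above percentile 98.8 of 10000 random lists matched on mean level in each comparison, and a shift of part of the class is a candidate explanation. Reads taken from RPL36A or HNRNPH2 cannot be told apart from it, although their summed mean was higher with YC-1 in all 4 comparisons, by up to 23.52 times the gain of the locus (8268 ± 596 to 17030 ± 701 in RBE at 16 h, SD, n = 3), which met the bound set beforehand against this explanation. That bound was wrong, because gains of 113 to 453 lie below the larger SD of the sum in every comparison, and RPL36A (1.15 in RBE at 16 h) is a ribosomal protein gene outside the list of 50 such genes, whose median there was 0.94.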
